A study of Mus musculus with 35 samples.

How the data were processed

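Stranded poly(A) messenger RNA libraries from wild-type mouse retina were sequenced as paired 100 bp reads on a NovaSeq instrument, per the labels' protocols. The labels give 35 samples in 7 groups: non-diabetic (ND, 6), non-diabetic repopulated (5), diabetic for 6, 8 and 10 weeks (5 each), 8 weeks with depletion (4) and 10 weeks with repopulation (5). The labels of the 8 and 10 week diabetic groups without depletion add PBS, and those of ND and the 6 week group do not. They do not say whether each sample is a separate animal. The series text speaks of non-diabetic retina at each time, while the labels hold a single ND group. The treatment that depleted microglia is a drug given in chow in the series text and DTx in the labels, and this conflict was left open.

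Base calls were converted with bcl2fastq and GRCm39 was the genome, per the labels; the versions, the aligner, the counting tool and the statistical test are not given in the sources used here. The authors deposited 8 tables of 2 groups each with 25655 genes. The log2 fold changes compare the first named group with the second as the authors deposited them, and the scaling between libraries is not stated. The signal level is the larger of the 2 group means, per the file headers, in a unit that is not stated. The p-value and FDR p-value per gene were deposited by the authors, and the FDR values equal Benjamini-Hochberg values over the genes that have one, within 0.000489. Genes without a deposited FDR value were not counted as tested. Values per library were not used here, so depth per sample, spread within groups, sample outliers, other splits of the samples and a fit of new models were not analysed here. The precision that the tables give is the standard error implied by each deposited p, with a median between 0.126 and 0.140 log2 in the 8 comparisons.

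The table of 10 weeks with repopulation against 10 weeks was deposited the other way round, and its sign was turned. The standard error of a gene was taken as its log2 fold change divided by the normal quantile of its p. Genes were called at an adjusted p under 0.05. Differences between 2 comparisons were tested with a normal test on the difference of log2 values, with variances added and Benjamini-Hochberg adjustment. Where both comparisons share the ND samples, added variances overstate the error. Gene lists, 44 of which were fixed before the data were examined, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal quantile of p at a preset correlation of 0.01, adjusted over the 43 lists with at least 5 measured members. Counts within a list are given from the adjustment over all genes and from an adjustment over the list alone. An inter-gene correlation estimated from the samples cannot be had without values per library, so 0.05 was used as the alternative: 114 of 145 list calls in the 8 comparisons held and 31 were lost. On log2 fold changes in place of the signed quantile 69 of the 145 held and 76 were lost. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

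Comparisons that share ND libraries were simulated with 100 draws (seed 7) without any effect, in which the shared controls alone linked the fold changes and as many top genes were taken as were called. Overlap is given against those draws and against independent lists. Transcript length and GC content were taken from a GRCm38 annotation by Ensembl number for 25600 genes (99.8%), and a cubic trend on both was fitted to genes with a level over 1.

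The rule for named genes was written before the data were examined. It takes, in each comparison, the 8 called genes with the largest rise and the 8 with the largest fall in the upper 60 percent of mean level. It adds the 4 members with the smallest p of each called list, a set of genes named in every comparison (Cx3cr1, P2ry12, Tmem119, Csf1r, C1qa, Gfap and Vegfa, and 1 that is not used here) and, for depletion and repopulation, every homeostatic microglia gene. Names of predicted genes, clones and pseudogenes (5061) were left out of naming. The text names only some of the genes that the rule takes. Where a gene outside this rule is named, the text says that it was picked after the values were seen.

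Alternatives fixed before the data were examined were thresholds of 0.01 and 0.10, an absolute log2 of at least 1, a filter leaving out the lowest 40 percent of mean level, predicted names left out, the list test on log2 fold changes, and Fisher's exact test of called members. Chosen after the data were seen were the removal of the length and GC trend, the omission of other-tissue lists, the differences between times, and the removal of the ND covariance from them.

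The steps were tested on simulated data with the implied standard errors of the tables. Changes in single genes were planted only where the level was over 1. Genes were drawn independently, so the list test was not tried under inter-gene correlation. Of genes given a change of log2 1, 93 to 97% were recovered in the 8 comparisons and 86% in a difference, and of those given log2 2, 97 to 100% and 95%. False calls made up 2.94 to 8.06% of calls in the comparisons and 6.22% in the difference, and the changed list was called in each case with at most 1 other list of 43.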

Results

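Messenger RNA was sequenced from the retinas of wild-type mice in 35 samples that fall into 7 groups. The non-diabetic group (ND) held 6 samples, and diabetic retina was taken after 6, 8 and 10 weeks of diabetes (D6, D8 and D10, 5 samples each). The labels of D8 and D10 add PBS, which those of ND and D6 do not, so D8 or D10 against ND or D6 also differ by that treatment. Microglia, the resident immune cells of the retina, were depleted for 2 weeks in the D8 depleted group (4 samples), and were left to return for 2 further weeks in the D10 repopulated and ND repopulated groups (5 samples each). The labels call the depleting treatment DTx while the series description names a drug given in chow, and the values do not settle which was used, so the text says only depletion. The values are 8 comparisons made by the authors, each with a log2 fold change, a p-value and the larger of both group means for 25655 genes, with no value per sample. Sequencing depth is therefore unknown, the unit of the means is not stated, and fold changes of genes close to 0 in one group depend on the authors' model and are no bounds. P-values measure the spread between samples, since the labels do not say that each sample is a separate animal. Library numbers place D8 and D10 in one run of numbers and the other 5 groups in another, with no date given, so each contrast of D8 or D10 with another of these groups also crosses that divide.

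**Figure D1:**
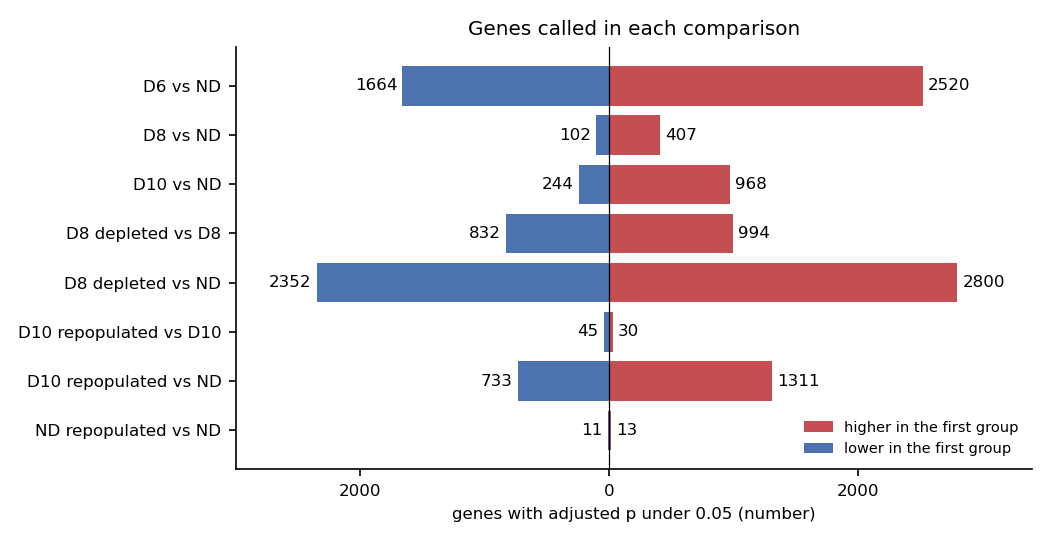
Number of genes with an adjusted p under 0.05 in each of the 8 comparisons (horizontal axis, genes), higher in the first-named group to the right in red and lower to the left in blue. D8 depleted against ND gave the most calls (2800 higher, 2352 lower) and ND repopulated against ND the fewest (13 higher, 11 lower).

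Retina after 6 weeks of diabetes was compared with ND to describe the tissue before depletion began. Inflammatory genes, together with lens crystallin genes, had the largest rises among the named genes. Saa3, an acute-phase serum amyloid gene, was higher by log2 8.48 (implied standard error 0.85) and the granulocyte growth factor gene Csf3 by 9.18 (1.23) in the authors' deposited table. The chemokine genes Cxcl10, Ccl2, Cxcl1 and Ccl7, which draw leukocytes into tissue, were higher there by 8.46, 7.73, 7.41 and 6.99 in the authors' deposited table. Of 32 measured genes of the cytokine, chemokine and adhesion list, 24 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 of 2.76 (cameraPR adjusted p = 1.35e-18).

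Reactive glia, interferon and glucocorticoid response genes moved the same way at 6 weeks. Of 25 gliosis genes 20 rose (22 adjusted over the list alone; median log2 2.36, adjusted p = 8.93e-29). Among them Lcn2, an iron-binding acute-phase gene, was higher by log2 6.30 and Gfap, the filament gene of astrocytes and stressed Muller glia, by 1.70 in the authors' deposited table. Interferon-stimulated genes rose in 23 of 28 cases (25 adjusted over the list alone; median 2.10, adjusted p = 8.24e-20), and antigen presentation genes in 11 of 18 (11; median 0.96, adjusted p = 1.04e-08). Glucocorticoid response genes rose in 13 of 17 cases (14 up and 1 down adjusted over the list alone; median 1.18, adjusted p = 6.93e-16). Fkbp5, a feedback gene of the glucocorticoid receptor, was higher by 1.28 and the metallothionein gene Mt2 by 4.54 in the authors' deposited table. Complement genes rose in 8 of 19 cases (11 up and 1 down adjusted over the list alone; adjusted p = 3.57e-05), led by the alternative pathway factor Cfb at log2 6.65 in the authors' deposited table.

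Several lists fell at 6 weeks in the test on signed p. In the planned list test on log2 fold changes the chaperone, synapse and ganglion cell lists did not pass (adjusted p = 0.0607, 0.133 and 0.235). Chaperone genes of the unfolded protein and heat shock list fell in 17 of 23 cases and rose in 1 (17 and 2 adjusted over the list alone; median -0.54, adjusted p = 2.9e-07). The heat shock gene Hspa1b was lower, log2 -1.33, while the small heat shock gene Hspb1 was higher, log2 3.55, in the authors' deposited table. Genes of synapses fell in 7 of 25 cases (7 adjusted over the list alone; median -0.20, adjusted p = 0.00019), with the vesicle gene Syn1 at log2 -0.56 in the authors' deposited table. Retinal ganglion cell markers fell in 5 of 18 cases (6 adjusted over the list alone; adjusted p = 0.0101), a call lost at a preset correlation of 0.05 (adjusted p = 0.0547). Rod genes did not pass as a list (median 0.02, adjusted p = 0.714). The homeostatic microglia list also did not pass (median -0.08, 2 higher and 3 lower of 25, 4 and 7 adjusted over the list alone; adjusted p = 0.477), although its purinergic receptor gene P2ry12 fell, log2 -1.08 in the authors' deposited table. Activated microglia genes rose in 11 of 25 cases (11 adjusted over the list alone; median 0.34, adjusted p = 0.000704), but not with genes of low level left out (adjusted p = 0.0522).

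Markers of other tissues moved beside the inflammatory genes at 6 weeks. Lens genes rose in 7 of 21 cases (7 adjusted over the list alone; median 1.82, adjusted p = 0.000468), and the hemoglobin gene Hbb-bs fell, log2 -2.03 in the authors' deposited table. Of 17876 genes with a deposited adjusted p, 4184 passed at 6 weeks, 2520 higher and 1664 lower, and 978 of them changed at least 2-fold. Over 43 lists 19 passed, and 16 of these held at a correlation of 0.05; a correlation estimated from the samples needs values per sample and was not analysed here.

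At 8 weeks the comparison of diabetic retina with ND again showed inflammatory genes at the top. Cxcl10 was higher by log2 8.30 (0.95), Saa3 by 8.20 (0.85) and Lcn2 by 5.51 (0.58) in the authors' deposited table. Cytokine, chemokine and adhesion genes rose in 21 of 32 cases and fell in 1 (24 and 1 adjusted over the list alone; median 2.53, adjusted p = 4.53e-44). Gliosis genes rose in 17 of 25 (21 alone; median 2.05, adjusted p = 2.53e-51) and interferon-stimulated genes in 21 of 28 with 1 fall (24 and 1 alone; median 1.83, adjusted p = 1.29e-42). Complement genes rose in 9 of 19 cases (11 adjusted over the list alone; adjusted p = 4.33e-15), among them C1qa, a microglial recognition gene of the classical pathway, at log2 0.72 in the authors' deposited table. Immediate early genes, which respond within minutes to neuronal activity, fell in 6 of 20 cases and rose in 2 (10 and 3 adjusted over the list alone; median -0.40, adjusted p = 1.21e-07), with Nr4a3 at log2 -2.73 in the authors' deposited table. The same list was lower in ND repopulated against ND (median -0.66), so a fall against ND also appears without diabetes. The call at 8 weeks did not hold in the list test on log2 fold changes (adjusted p = 0.127). The homeostatic microglia list did not pass (median -0.04, adjusted p = 0.316), but with genes of low level left out it passed upward (adjusted p = 0.00357). Rod genes did not pass (median -0.06, adjusted p = 0.943).

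Lens and blood genes fell at 8 weeks while the inflammatory genes rose. The lens transcription factor Foxe3 was lower, at log2 -8.42, the lens membrane gene Mip at -7.59 and the crystallin gene Cryaa at -6.22 in the authors' deposited table. Lens genes fell in 13 of 21 cases (15 adjusted over the list alone; median -4.64, adjusted p = 3.43e-20) and blood cell genes in 4 of 9 (5; median -2.70, adjusted p = 3.7e-08). Pigment epithelium genes shifted down as a list (median -0.38, adjusted p = 0.00443) with 4 lower and 1 higher adjusted over the list alone. Of 17495 genes tested 509 passed, 407 higher and 102 lower, 338 of them by at least 2-fold, and 303 genes passed when genes of low level were left out. Of 18 lists that passed 15 held at a correlation of 0.05, and the synapse, apoptosis and histone lists did not (adjusted p = 0.076, 0.113 and 0.0936).

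**Figure D2:**
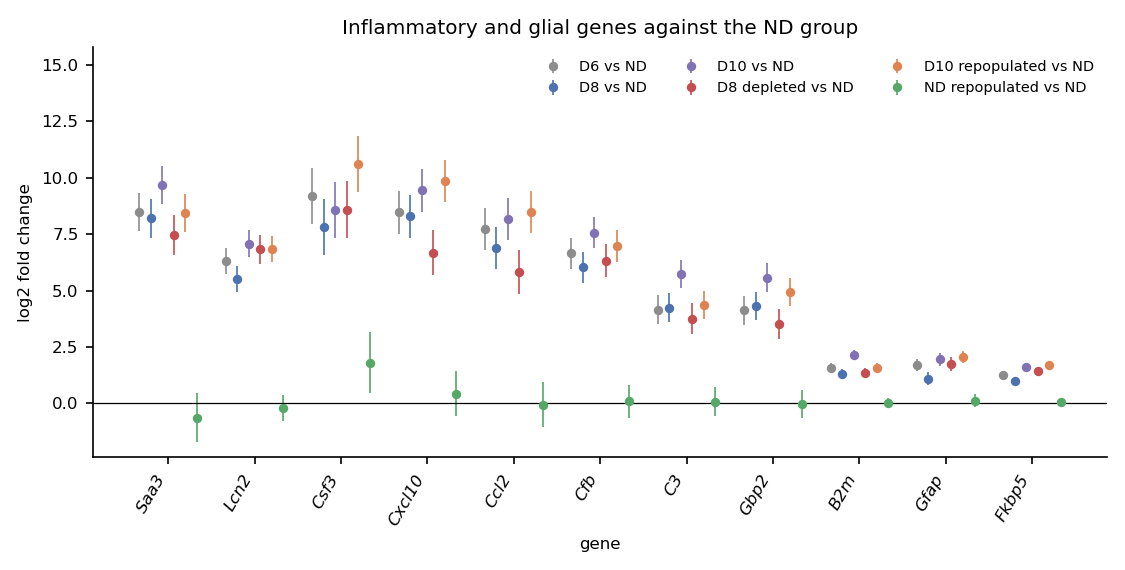
Log2 fold change against ND (vertical axis) of 11 inflammatory, glial and glucocorticoid response genes (horizontal axis) in the 5 diabetic groups and in ND repopulated; points are the deposited values and bars 1 implied standard error each way. Saa3 lies at 8.48, 8.20 and 9.66 after 6, 8 and 10 weeks of diabetes.

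After 10 weeks the same groups of genes were higher than in ND, and Saa3 reached log2 9.66 (0.85), the acute-phase gene Orm2 8.63 (1.90) and Cfb 7.57 (0.70) in the authors' deposited table. Interferon-stimulated genes rose in 27 of 28 cases (27 adjusted over the list alone; median 2.87, adjusted p = 1.31e-71), and gliosis genes in 21 of 25 (22; median 2.86, adjusted p = 9.77e-75). Antigen presentation genes rose in 11 of 18 cases (12 up and 1 down adjusted over the list alone; median 1.51, adjusted p = 1.34e-28), with B2m, the shared chain of class I molecules, at log2 2.15 in the authors' deposited table. Activated microglia genes rose in 12 of 25 (15 adjusted over the list alone; median 0.90, adjusted p = 4.88e-15). The homeostatic list did not pass (median -0.04, adjusted p = 0.942), but passed upward with genes of low level left out (adjusted p = 9.94e-06), with P2ry12 lower, log2 -1.80, and C1qa higher, 0.98, in the authors' deposited table. Muller glia markers fell in 6 of 18 cases and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0104, or 0.0621 at a correlation of 0.05). Rlbp1, a retinoid carrier of Muller glia and pigment epithelium, was lower, at log2 -1.17, and Slco1a4, a transporter of the brain and retinal endothelium, at -2.01 in the authors' deposited table. Cholesterol and lipid genes fell in 9 of 24 cases and rose in 1 (12 and 1 adjusted over the list alone; median -0.27, adjusted p = 1.57e-05). That call did not hold in the list test on log2 fold changes (adjusted p = 0.235).

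Blood cell genes fell beside these changes at 10 weeks, in 5 of 9 cases (5 adjusted over the list alone; median -2.79, adjusted p = 2.53e-05), while the lens list did not pass (median -0.34, adjusted p = 0.722). Of 17317 genes tested 1212 passed, 968 higher and 244 lower, 717 of them by at least 2-fold, and 671 passed with genes of low level left out. Of 18 lists that passed 12 held at a correlation of 0.05; besides Muller glia the lost lists were border macrophages, pericytes, synapse, extracellular matrix and histones (adjusted p = 0.0986, 0.0952, 0.0937, 0.108 and 0.0986).

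At all 3 times 354 genes were higher and 49 lower than in ND. Their median log2 at 6, 8 and 10 weeks was 1.82, 1.62 and 2.45 for the genes that rose and -0.78, -0.67 and -0.70 for those that fell. The comparisons share the ND samples, which gives overlap with no effect at all. Of the genes called higher, 372 were shared between 6 and 8 weeks against 58.6 for independent lists and 205 in 100 simulations of unchanged groups against shared controls (at most 236). Between 6 and 10 weeks 657 were shared (141 independent, 425 simulated, at most 454) and between 8 and 10 weeks 380 (22.8 independent, 115 simulated, at most 141). Of genes called lower, 55, 171 and 56 were shared in these pairs, against 49.95, 106 and 15.6 simulated (at most 64, 125 and 26) and 9.70, 23.4 and 1.44 for independent lists, so the 55 shared between 6 and 8 weeks lie within what shared controls alone gave. The covariance of the fold changes was 0.340, 0.466 and 0.394 for the 6 and 8, 6 and 10, and 8 and 10 week pairs, and simulated shared controls gave 0.108, 0.0927 and 0.0966. The differences, 0.232, 0.373 and 0.297, are what independent error in the shared controls leaves over. Besides a shared effect they may hold features of the ND samples common to many genes. For the 8 and 10 week pair they may also hold PBS and the run of library numbers. The controls could not be split without values per sample, so part of the shared calls may come from them.

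Tests of the difference between times, and the genes named from them, were chosen after the data were seen. With errors taken as independent, 4 genes differed between 8 and 6 weeks and 2 between 10 and 6 weeks, all lower at the later time. The normal test then called 0 genes between 10 and 8 weeks, where 219 had an unadjusted p under 0.05. Both comparisons of each pair share the ND samples, whose error cancels in the difference. Errors taken as independent are therefore too large, and these low counts do not show that the times hardly differ. H1f8, an oocyte linker histone gene called at both times, had a log2 difference of -6.29 at 8 weeks and -6.08 at 10 weeks (standard errors 1.07 and 1.07, from the authors' deposited table). Wfikkn1, a protease inhibitor gene, had -3.63 and -3.84, and Mtmr10, called at 8 weeks alone, -0.90 (from the authors' deposited table); the other gene was the predicted gene Gm20521. H1f8, Wfikkn1 and Mtmr10 lie next to other genes on the same strand, and whether reads of those genes enter these values was not tested. Taking off the covariance that the ND samples bring raised the counts to 614 (109 higher and 505 lower), 511 (150 higher and 361 lower) and 3 genes. The 3 genes of the 8 to 10 week contrast were A2m, Gpnmb and H2ac19, with log2 differences of 1.66, 1.52 and 6.34 computed from the authors' deposited table. By list, interferon-stimulated genes were higher at 10 than at 8 weeks (median difference 1.11, adjusted p = 9.69e-33), as were gliosis genes (0.93, 7.8e-27) and lens genes (4.52, 4.25e-45). Lens genes were lower at 8 than at 6 weeks (median difference -6.74, adjusted p = 6.63e-39).

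The D8 depleted group was compared with D8 to see what 2 weeks of depletion changed in diabetic retina. Microglial genes, together with lens crystallin genes, had the largest falls among the named genes, and the microglial falls check the label of the group. The fractalkine receptor gene Cx3cr1 was lower, at log2 -6.98 (0.85), the growth factor receptor gene Csf1r, on which microglia depend, at -3.15 (0.38) and C1qa at -6.92 (0.57) in the authors' deposited table. Of 25 homeostatic microglia genes 20 fell (21 down and 1 up adjusted over the list alone), with a median log2 of -3.23 (adjusted p = 4.12e-52). The chemokine genes Ccl12 and Ccl3 were lower, at log2 -7.35 and -4.21 in the authors' deposited table. Cytokine, chemokine and adhesion genes fell in 5 of 32 cases (5 adjusted over the list alone; median -0.66, adjusted p = 8.61e-05). Complement genes fell in 6 of 19 and rose in 1 (6 and 3 alone; adjusted p = 4.13e-06). Neither gliosis genes (median -0.23, adjusted p = 0.583) nor interferon-stimulated genes (median 0.07, adjusted p = 0.609) passed as lists.

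Neuronal lists were lower after depletion in the test on signed p, though not in the planned test on log2 fold changes. Synapse genes fell in 6 of 25 cases (8 adjusted over the list alone; median -0.27, adjusted p = 8.28e-07), amacrine and horizontal cell genes in 5 of 21 (7 down and 1 up alone; median -0.32, adjusted p = 0.000573) and ganglion cell genes in 3 of 18 (4 alone; median -0.23, adjusted p = 0.0029). Slc17a6, the glutamate transporter gene of ganglion cells, was lower, at log2 -0.76, and the cone arrestin gene Arr3 at -0.99 in the authors' deposited table. Cone genes fell in 4 of 16 cases (4 alone; adjusted p = 0.00548), while the rod and bipolar lists lost their calls at a correlation of 0.05 (adjusted p = 0.076 and 0.113). Chaperone genes fell in 8 of 23 and cholesterol genes in 8 of 24 (8 and 10 adjusted over each list alone; adjusted p = 0.000391 and 8.61e-05). Genes of ribosomal proteins rose in 16 of 32 cases (26 adjusted over the list alone; median 0.36, adjusted p = 1.14e-12), and ketone and fatty acid oxidation genes in 7 of 21 (11 up and 1 down alone; adjusted p = 0.000573). Fold changes in this comparison fell with transcript length (Spearman -0.283 across 12125 genes, which are not independent replicates) and rose with GC content (0.261). With both trends removed, 1452 genes passed and 21 of the 23 list calls held, among them those of ribosomal, synapse, rod, cone, bipolar, amacrine and ganglion cell genes, while oxidative phosphorylation and oxidative stress were lost. Tested on log2 fold changes instead, the synapse, amacrine, ganglion cell, cone, rod and bipolar lists did not pass (adjusted p = 0.216, 0.194, 0.325, 0.351, 0.351 and 0.404), nor did the chaperone, cholesterol, ribosomal and ketone lists (0.308, 0.26, 0.26 and 0.183).

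Other tissue markers moved with the depletion contrast. Lens genes fell in 13 of 20 cases (15 down and 1 up adjusted over the list alone; median -2.65, adjusted p = 5.75e-20). Cornea and iris genes rose in 4 of 17 (5 alone; adjusted p = 0.00597), pigment epithelium genes in 6 of 19 (6 alone; adjusted p = 0.00597) and blood cell genes in 4 of 8 (4 alone; adjusted p = 0.00378). Krt16 and Krt5, keratins of surface epithelium, were higher by log2 5.59 and 2.51 in the authors' deposited table. Of 16982 genes tested 1826 passed, 994 higher and 832 lower, 551 of them by at least 2-fold; leaving out the lists of other tissues left 1785. Of 23 lists that passed 17 held at a correlation of 0.05, the glycolysis, oxidative phosphorylation, oxidative stress and clock lists being the others lost (adjusted p = 0.107, 0.136, 0.128 and 0.07).

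**Figure D3:**
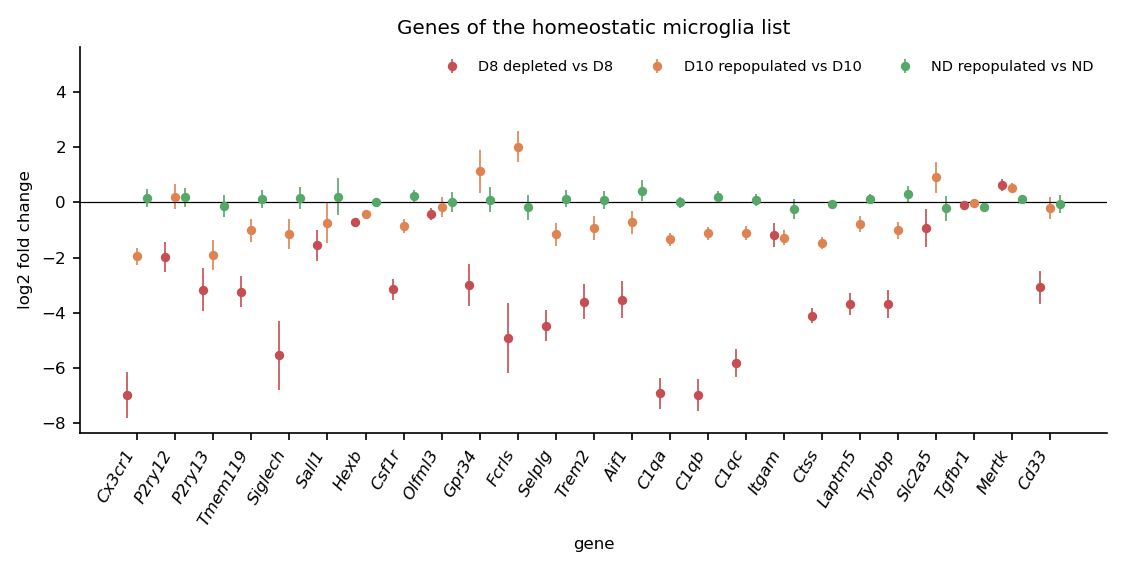
Log2 fold change (vertical axis) of the 25 homeostatic microglia genes (horizontal axis) for D8 depleted against D8, D10 repopulated against D10 and ND repopulated against ND; points are the deposited values and bars 1 implied standard error each way. The list medians are -3.23, -0.86 and 0.10.

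Depleted diabetic retina was also set against ND, which shows both effects together. Several inflammatory genes were above ND after depletion: Csf3 was higher by log2 8.58 (1.27), Saa3 by 7.45 (0.89) and Lcn2 by 6.82 (0.62) in the authors' deposited table. Interferon-stimulated genes rose in 22 of 28 cases (24 adjusted over the list alone; median 1.92, adjusted p = 3.03e-13), gliosis genes in 16 of 25 (17; median 1.75, adjusted p = 1.84e-12) and cytokine genes in 15 of 32 with 1 fall (16 and 1; median 1.04, adjusted p = 7.48e-05). Complement genes rose in 6 of 19 and fell in 4 (7 and 4 adjusted over the list alone), and that list (median -0.25, adjusted p = 0.602) and activated microglia (median 0.15, adjusted p = 0.873) did not pass, although both had passed in D8 against ND, activated microglia not with genes of low level left out (adjusted p = 0.13). Homeostatic microglia genes fell in 20 of 25 and rose in 1 (22 and 1 adjusted over the list alone; median -3.44, adjusted p = 7.76e-34); the riser was Mertk, a phagocytic receptor that other retinal cells also express, at log2 0.91 in the authors' deposited table. Synapse genes fell in 12 of 25 cases (12 alone; median -0.36, adjusted p = 6.79e-07) and immediate early genes in 10 of 20 with 1 rise (11 and 1; median -0.80, adjusted p = 3.18e-05), the latter list being lower in ND repopulated as well. Fold changes here also followed transcript length and GC content (Spearman -0.253 and 0.2197), and with both trends removed 4608 genes passed and the synapse list kept its call. In the planned list test on log2 fold changes the synapse list did not pass (adjusted p = 0.0884). The hypoxia-regulated growth factor gene Vegfa was lower, at log2 -0.56 and the Muller glia potassium channel gene Kcnj10 at -1.01 in the authors' deposited table. Ketone and fatty acid oxidation genes rose in 13 of 21 and fell in 1 (13 and 1 adjusted over the list alone; median 0.59, adjusted p = 9.1e-05, or 0.137 in the list test on log2 fold changes). Beside them lens genes fell in 17 of 21 cases (19 alone; median -6.35, adjusted p = 1.42e-13), with Cryaa at log2 -9.15 in the authors' deposited table. Of 18102 genes 5152 passed, 2800 higher and 2352 lower, 1374 of them by at least 2-fold. Of 19 lists that passed 15 held at a correlation of 0.05; the amacrine, glycolysis, oxidative stress and histone lists did not (adjusted p = 0.075, 0.0501, 0.138 and 0.082).

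D10 repopulated was compared with D10 to see what remained different once microglia had returned. Most homeostatic microglia genes were lower than in D10, though by less than after depletion. Fcrls of that list went the other way, at log2 2.01 in the authors' deposited table. C1qa was above ND in D10 and did not pass against ND after repopulation, so its fall here starts from a raised level. Cx3cr1 was lower, at log2 -1.96 (0.32), the lysosomal protease gene Ctss at -1.48 (0.21) and C1qa at -1.34 (0.23) in the authors' deposited table. Of 25 homeostatic genes 6 fell (15 down and 2 up adjusted over the list alone; median -0.86, adjusted p = 5.01e-17), while Csf1r and Tmem119 stood at -0.86 and -1.02 with adjusted p = 0.124 and 0.438 in the authors' deposited table. Complement genes fell in 3 of 19 cases (7 alone; median -0.58, adjusted p = 7.58e-13), gliosis genes in 3 of 25 (10 alone; median -0.38, adjusted p = 9.13e-13), and chaperone genes in 1 of 23 (11 alone; median -0.42, adjusted p = 3.32e-11). The chaperone call did not hold in the list test on log2 fold changes (adjusted p = 0.0733). The copper-binding plasma gene Cp was lower, at log2 -0.85 and Gpnmb, a gene of the activated microglia list, at -1.30 in the authors' deposited table. Gpnmb stood at log2 0.69 on depletion in the authors' deposited table, where C1qa fell, so its fall here is not read as a microglial change. The interferon gene Mx1 was higher by 2.82 and the cytokine gene Il19 by 3.28 in the authors' deposited table, but the interferon list did not pass (median -0.02, adjusted p = 0.665). Visual cycle genes, made mostly by pigment epithelium, rose in 3 of 16 cases (6 alone; median 0.15, adjusted p = 0.000248). That list was also higher in ND repopulated against ND (median 0.24, adjusted p = 2.29e-05), with adjusted p = 0.973 for the difference, and pigment epithelium genes rose in 3 of 19 cases and fell in 1 (7 and 4 alone; adjusted p = 0.0742). Blood cell genes rose in 4 of 9 (5 alone; median 2.93, adjusted p = 2.69e-14) and a lens gene fell in 1 of 21 (4 alone; median -1.14, adjusted p = 3.1e-06). Of 16826 genes 75 passed, 30 higher and 45 lower, 45 of them by at least 2-fold, and 60 passed with the lists of other tissues left out. Of 19 lists that passed 15 held at a correlation of 0.05, and the leukocyte, ketone, cell cycle and histone lists did not (adjusted p = 0.12, 0.0869, 0.14 and 0.0966).

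Against ND, repopulated diabetic retina had higher inflammatory genes and lower homeostatic microglial genes, while activated microglia genes rose in 9 of 25 cases (10 adjusted over the list alone; median 0.40, adjusted p = 1.05e-05). Csf3 was higher by log2 10.60 (1.23), Cxcl10 by 9.85 (0.95) and the cytokine gene Il6 by 9.22 (1.46) in the authors' deposited table. Cytokine, chemokine and adhesion genes rose in 25 of 32 cases and fell in 1 (26 and 1 adjusted over the list alone; median 3.25, adjusted p = 3.26e-33), and interferon-stimulated genes rose in 23 of 28 (26; median 2.97, adjusted p = 1.13e-54). Homeostatic microglia genes fell in 12 of 25 and rose in 1 (13 and 1 adjusted over the list alone; median -0.64, adjusted p = 3.15e-08), but the list did not pass with genes of low level left out (adjusted p = 0.393). Within it Cx3cr1, P2ry12 and Tmem119 were lower, at log2 -2.06, -1.59 and -1.62, while C1qa at -0.35 did not pass (adjusted p = 0.265) in the authors' deposited table. Chaperone genes fell in 14 of 23 and rose in 2 (15 and 2 alone; median -0.54, adjusted p = 1.25e-08). Ketone and fatty acid oxidation genes rose in 11 of 21 (12 alone; median 0.41, adjusted p = 1.76e-05). Barrier genes fell in 5 of 22 and rose in 2 (7 and 2 alone; adjusted p = 0.00587), a call lost at a correlation of 0.05 (adjusted p = 0.0529). The lens list (median -1.06, adjusted p = 0.0626) and the blood list (median 0.16, adjusted p = 0.771) did not pass beside these groups. Of 17495 genes 2044 passed, 1311 higher and 733 lower, 814 of them by at least 2-fold, and 13 of the 17 lists that passed held at a correlation of 0.05, with oxidative stress, synapse and apoptosis also lost (adjusted p = 0.0529, 0.123 and 0.0715).

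**Figure D4:**
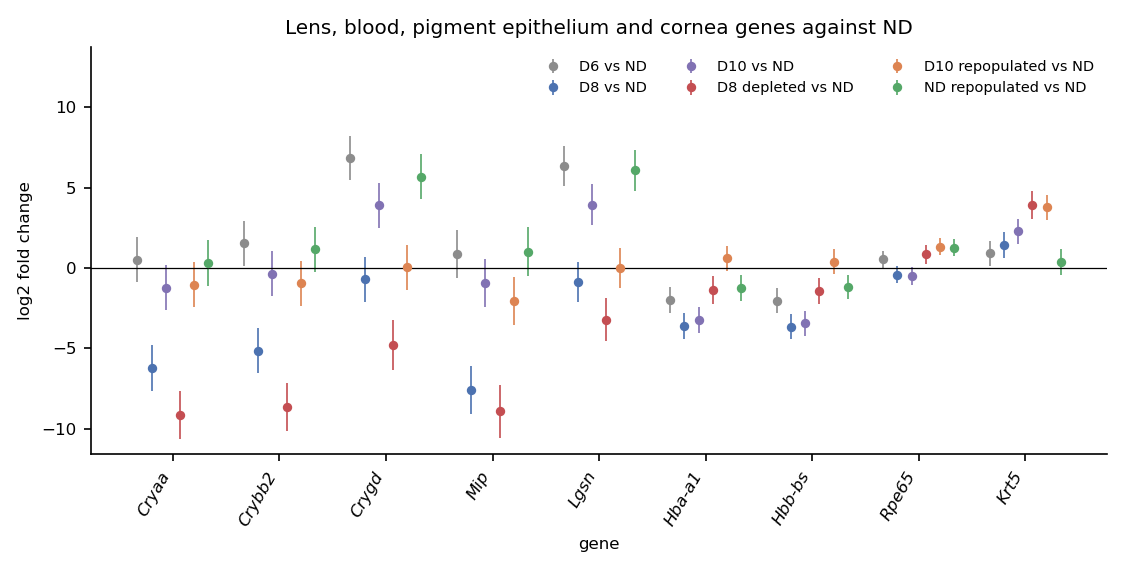
Log2 fold change against ND (vertical axis) of 9 genes of lens, blood, pigment epithelium and cornea (horizontal axis) in the 5 diabetic groups and in ND repopulated; points are the deposited values and bars 1 implied standard error each way. Cryaa lies at -6.22 in D8 and -9.15 in D8 depleted, and Hbb-bs at -3.64 in D8 and -3.45 in D10.

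In non-diabetic retina, no gene of the homeostatic microglia list passed after repopulation in the authors' test, and the list itself did not pass. Cx3cr1 stood at log2 0.16 (adjusted p = 1) and C1qb at 0.18 (1) in the authors' deposited table, and the homeostatic list had a median of 0.10 (adjusted p = 0.412). Immediate early genes fell in 6 of 20 cases (12 adjusted over the list alone; median -0.66, adjusted p = 1.73e-46). Egr1 and Fos, transcription factors induced by neuronal activity, were lower, at log2 -2.61 (0.41) and -1.61 (0.31) in the authors' deposited table. Lens genes rose in 3 of 21 (6 alone; median 1.45, adjusted p = 2.19e-17), with Lgsn, a lens fibre gene, at log2 6.08 and Hspb1 at 2.92 in the authors' deposited table. Blood cell genes (median -0.93, adjusted p = 0.0161) and leukocyte genes (median -0.67, adjusted p = 7.34e-05) shifted down as lists, and skeletal muscle genes shifted up (median 0.99, adjusted p = 1.98e-06). Fold changes fell with transcript length here too (Spearman -0.238). Of 15402 genes 24 passed, 13 higher and 11 lower, 13 of them by at least 2-fold. Of 12 lists that passed 11 held at a correlation of 0.05, the cholesterol list being lost (adjusted p = 0.167).

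Whether repopulation left different marks in diabetic and non-diabetic retina was tested as a difference of both contrasts, which share no samples. Of 18263 genes 28 differed, 12 higher and 16 lower in diabetic retina. Cx3cr1 differed by log2 -2.12 (standard error 0.45, adjusted p = 0.00324), C1qa by -1.34 (0.30, 0.0097), C1qb by -1.31 (0.31, 0.0162) and Ctss by -1.41 (0.26, 0.000311), all computed from the authors' deposited table. Among homeostatic microglia genes 4 of 25 were lower (12 lower and 1 higher adjusted over the list alone; median difference -1.04, adjusted p = 1.5e-15). Egr1 differed the other way, by 2.38 (adjusted p = 0.00112, from the authors' deposited table). Lens genes (median -2.32, adjusted p = 3.01e-20) and blood cell genes (4.32, 3.77e-15) differed in the same test. Hemoglobin genes had a median log2 of -3.40 in D10 and 0.41 in D10 repopulated, each against ND. The run of library numbers parts D10 from D10 repopulated but not ND from ND repopulated, so this difference also holds it. Among these groups the label of D10 alone names PBS, and whether the repopulated groups received it is not stated. If they did, PBS parts ND from ND repopulated instead, so this difference may hold PBS either way. No non-diabetic group was taken at the end of depletion, so the loss of microglia there was not measured.

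The effect of depletion on diabetic retina was tested against the effect that remained after repopulation. Of 17792 genes 107 differed, 59 with a higher log2 under depletion and 48 with a lower one. C1qb differed by -5.84 (standard error 0.62, adjusted p = 4.01e-17), Cx3cr1 by -5.02 (0.90, 5.07e-05) and Csf1r by -2.29 (0.46, 0.000748), computed from the authors' deposited table. Homeostatic microglia genes were lower under depletion in 12 of 25 cases (17 adjusted over the list alone; median difference -2.66, adjusted p = 4.36e-42). Gpnmb differed by 1.98 and the ganglion cell gene Slc17a6 by -0.96 (adjusted p = 9.33e-06 and 0.000924, from the authors' deposited table). The epithelial gene Psca also differed (4.26, adjusted p = 2.98e-08, from the authors' deposited table), while the cornea list had a median difference of 0.73 (adjusted p = 0.205). Other epithelial genes, picked after the values were seen, were among those with a higher log2 under depletion. Krt75, Prss27 and Lypd2 differed by 4.28, 3.71 and 3.45, computed from the authors' deposited table. Like Psca they were higher on depletion and lower on repopulation, so the 107 genes are not all read as retinal.

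Of the 968 genes higher at 10 weeks than in ND, 705 were also higher and 1 lower in D10 repopulated against ND. Against D10 itself 31 of them were lower and 5 higher after repopulation, with a median log2 of -0.20, and 98.97% kept their sign against ND. The ND samples enter the first of these lookups and the D10 samples the second. Genes picked at 8 weeks free the second alone from shared samples. Of 407 genes higher in D8, 16 were lower and 4 higher in D10 repopulated against D10 (median log2 -0.18). D8 and D10 share a run of library numbers that ND and D10 repopulated lie outside of, so this lookup is not free of it. The labels of D8 and D10 also share PBS, which those of ND and D10 repopulated do not name. Whether D10 repopulated received it is not stated, so the lookup may not be free of PBS. Of 832 genes that fell on depletion 14 were lower in D10 repopulated against D10, and of 994 that rose 17 were higher and 5 lower (median log2 -0.07 and 0.15). The 10 week lists and those of D10 repopulated against ND shared 705 higher genes, against 73.3 for independent lists and 276 simulated, with covariances of 0.520 observed and 0.0942 simulated, a difference of 0.426. For D8 and D8 depleted, each against ND, 317 were shared against 65.1 independent and 205 simulated, with covariances of 0.418 and 0.110, a difference of 0.307.

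Genes called on depletion also moved at 6 weeks of diabetes, in a pair of comparisons with no group in common. Of genes tested in both, 588 were higher in D6 against ND and in D8 depleted against D8, where independent lists would share 147, and 344 were lower in both against 81.5. In the opposite way, 50 genes that fell on depletion were higher at 6 weeks and 3 that rose were lower. Some other pairs without a common group overlapped too: depletion and D10 repopulated against ND shared 294 higher genes where 76.8 would be shared by independent lists (Spearman 0.364), and D6 against ND correlated with D10 repopulated against D10 (0.339), as did depletion (0.272). For D6 against ND and D10 repopulated against D10, 16 higher genes were shared where independent lists would share 4.48, and 4 lower genes against 4.45. For depletion and D10 repopulated against D10, 17 higher genes were shared against 1.78 and 14 lower genes against 2.24. Depletion and ND repopulated against ND shared 0 higher genes (0.806 for independent lists) and 2 lower (0.593) but had a Spearman correlation of 0.240, and D10 repopulated against D10 and ND repopulated against ND shared 0 in either direction (Spearman 0.0195). Some shared genes were picked after the values were seen. Txnip, a glucose-responsive gene, was higher by log2 1.80 and 1.16 in the 6 week and depletion contrasts, and Arrdc2, a glucocorticoid target, by 1.46 and 1.60 in the authors' deposited table. The synaptic gene Syn1 was lower, at log2 -0.56 and -0.65 in the authors' deposited table. Glucocorticoid, ribosomal, ketone and oxidative stress lists passed upward in both contrasts, and chaperone, cholesterol, synapse, glycolysis and ganglion cell lists downward. Lens, complement, cytokine and activated microglia lists passed in opposite directions. On depletion 5 of 17 glucocorticoid response genes rose (median 0.26, cameraPR adjusted p = 0.000208, or 0.188 on log2 fold changes). A shared cause was not tested. The fold changes had a Spearman correlation of 0.555 across 12109 genes, which are not independent replicates, and 0.586 with length and GC trends removed.

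**Figure D5:**
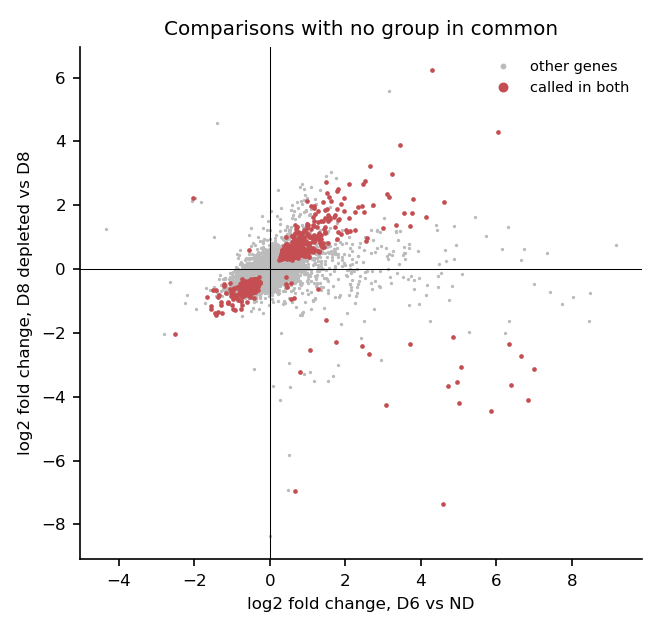
Log2 fold change of D6 against ND (horizontal axis) and of D8 depleted against D8 (vertical axis), 1 point per gene with a group mean level over 1 in some group; red points passed an adjusted p of 0.05 in both comparisons. The rank correlation was 0.555.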

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

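The tests of time differences and of every explanation below were chosen after the results were seen; the test of repopulation in diabetic against non-diabetic retina was planned.

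The first pattern is the set of 354 genes higher than ND at 6, 8 and 10 weeks of diabetes, 21 of which are on the cytokine, chemokine and adhesion list. ND libraries standing apart on their own would lift these genes in ND repopulated as well, but their median there was 0.0764, and more blood in diabetic retina is argued against by hemoglobin genes, whose highest median at the 3 times was -2.003. Microglia as the main source of the transcripts is argued against for the set by a median of 0.0271 on depletion, where 33 fell and 28 rose. For the 21 listed members the median was -1.09, with 8 of them below -1.62, and 4 were called lower and 0 higher. For these genes a microglial source and an indirect loss cannot be told apart. The D8 samples enter both the pick of the genes and the depletion contrast, so part of a fall may come from them. A cause outside the retina, such as a systemic inflammatory state that the labels do not describe, was not tested.

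Lens genes form the second pattern, higher than ND at 6 weeks and in ND repopulated and lower at 8 weeks and on depletion. If lens tissue entered some dissections, lens genes other than crystallins would move with the crystallins. They did so in 6 of 6 comparisons with a called lens list, by at least 1.80. These genes are on the list whose call picked the comparisons, so part of this is built in. Without a call, crystallin and other lens medians against ND were -0.38 and 0.48 in D10, and -0.99 and -1.39 in D10 repopulated. Lens tissue carried into some groups is a candidate explanation, and crystallin changes are not read as a retinal response. No biological explanation was tested.

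The overlap of depletion with 6 weeks of diabetes is the third pattern. Length or GC content does not account for it, since the correlation was 0.586 after both trends were removed, nor does lens tissue, with lens medians of 1.82 at 6 weeks and -2.65 on depletion. Fewer microglia at 6 weeks is argued against by a homeostatic median of -0.0847. Leaving out genes that follow an abundant gene left a correlation of 0.555 over 11911 of 12109 genes. So few genes were left out that the correlation could hardly have fallen, so this does not decide on reads that run on. Handling or library day cannot be told apart from the groups, because 0 labels give a day, although the library numbers part D8 from the depleted group and do not part D6 from ND.

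The effect of repopulation differed between diabetic and non-diabetic retina for 28 genes, by a test of the difference itself. The run of library numbers parts D10 from D10 repopulated but not ND from ND repopulated. Among these groups the label of D10 alone names PBS, and whether the repopulated groups received it is not stated. If they did, PBS parts ND from ND repopulated instead. Neither the run of numbers nor PBS can be told apart from diabetes in this difference. The log2 difference was -2.12 for Cx3cr1, -1.34 for C1qa, -1.31 for C1qb, -1.41 for Ctss, 2.38 for Egr1, 5.01 for Hbb-bs, -10.05 for Lgsn and -9.58 for Crygd, computed from the authors' deposited table. Among lists the median difference was -1.04 for homeostatic microglia, -0.29 for activated microglia, -0.69 for complement, -0.29 for gliosis, -0.30 for antigen presentation and -0.51 for chaperones. None of the 28 genes is on the activated microglia or gliosis list, so those are small shifts of whole lists. The median difference was 1.99 for lymphocytes and neutrophils, 4.32 for blood, -2.32 for lens and 0.14 for ganglion cells. It was 0.20 for mitochondrially encoded genes, -0.18 for ribosomal proteins, -0.11 for oxidative stress, 0.40 for immediate early genes, 0.23 for clock genes, 0.10 for glucocorticoid response and -0.11 for histones. Of 17 list calls in this difference 13 held at a correlation of 0.05; ganglion cells, antigen presentation, oxidative stress and glucocorticoid response did not (adjusted p = 0.0567, 0.0567, 0.143 and 0.103).

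Between times of diabetes, 4 genes differed at 8 against 6 weeks and 2 at 10 against 6 weeks with errors taken as independent. The shared ND samples make those errors too large. With the covariance of the shared ND samples taken off, 614 and 511 genes differed. H1f8 had a difference of -6.29 at 8 weeks, computed from the authors' deposited table. List medians at 8 against 6 weeks were -0.62 for pigment epithelium, -6.74 for lens, -1.61 for blood and -0.66 for glucocorticoid response. At 10 against 6 weeks they were 0.59 for gliosis, -2.17 for lens, -1.24 for blood and 0.74 for interferon-stimulated genes. At 10 against 8 weeks they were 0.50 for activated microglia, 0.50 for border macrophages, 0.93 for gliosis, 4.52 for lens, 0.89 for cytokines, 1.11 for interferon-stimulated genes, 0.60 for antigen presentation and 0.60 for glucocorticoid response. At a correlation of 0.05, 7 of 18, 14 of 17 and 18 of 24 list calls held in these 3 differences; pigment epithelium and blood were lost at 8 against 6 weeks (adjusted p = 0.125 and 0.104) and blood at 10 against 6 weeks (0.0823). D8 and D10 also differ from D6 by the PBS in their labels.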

How the results depend on the processing

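The removal of length and GC trends, the omission of other-tissue lists and the covariance of shared ND samples were chosen after the data were seen; the other alternatives were planned. At a threshold of 0.01 the genes called numbered 2401 in D6, 310 in D8, 3354 in D8 depleted and 1190 in D10 repopulated against ND, 739 in D8 depleted against D8 and 38 in D10 repopulated against D10, where 0.10 gave 144. With an absolute log2 of at least 1 the counts against ND were 978 for D6, 338 for D8, 717 for D10, 1374 for D8 depleted, 814 for D10 repopulated and 13 for ND repopulated, with 551 on depletion and 45 on repopulation in diabetic retina. These counts are lower by construction. Leaving out genes of low level gave 303 genes in D8 and 671 in D10; the cause was not tested.

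Lists tested on log2 fold changes passed in 11 cases for D6, 11 for D8, 9 for D10 and 11 for D8 depleted against ND, 9 on depletion, 7 on repopulation in diabetic and 6 in non-diabetic retina. Fisher's exact test called 11 in D8, 7 in D10 repopulated against D10 and 2 in ND repopulated. Of 145 list calls 69 held on log2 fold changes and 139 with trends removed, and 122 of 141 with genes of low level left out. Of 774 named-gene results 706 held at 0.01 and 746 with trends removed.

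The difference of depletion and repopulation gave 249 genes at 0.10 (124 higher, 125 lower) and 68 with genes of low level left out (33 and 35), against 59 and 48. The larger direction also changed for D10 repopulated against D10 at an absolute log2 of at least 1 (23 higher, 22 lower, against 30 and 45), and for ND repopulated at 0.01 (8 and 11) and with other-tissue lists left out (9 and 11), against 13 and 11. With the ND covariance taken off, 614, 511 and 3 genes differed at 8 against 6, 10 against 6 and 10 against 8 weeks. Genes shared by the 3 times numbered 250 at 0.01 and 268 at an absolute log2 of at least 1, against 403. Of genes called at 10 weeks, 564 and 543 were called the same way in D10 repopulated under these settings, against 867, and 14 depletion calls recurred on repopulation at 0.01, against 31. Refits with other tools or pseudocounts, counts without a filter, leaving out each sample and an estimated correlation need values per sample and were not run.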

Other observations

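The tests of neighbouring genes were chosen after the results of single genes were seen.

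Genes that follow a far more abundant gene on the same strand were called higher at 6 weeks in 146 of 737 cases (19.8%, median log2 0.24). The single genes that led to the test, Wfikkn1, Lat2, Cabyr and Mtmr10 among them, were left out of each place, and not all of them have a neighbour 10 times as abundant. All other places beside such a gene gave 175 of 1385 (12.6%, median 0.07; Fisher's exact test, p = 1.88e-05). The closest control, genes with the abundant gene behind them on the same strand and none before, gave 73 of 459 (15.9%, median 0.14), a difference that did not pass (Fisher's exact test, p = 0.0914). Against all other places the share was 8.39% and 5.39% on depletion (p = 0.00876 by Fisher's exact test), where the closest control gave 5.93% (p = 0.139 by Fisher's exact test). It was 17.8% and 17.1% in D8 depleted against ND (Fisher's exact test, p = 0.718), 1.63% and 1.66% in D8 against ND, and 4.75% and 6.37% in D10 against ND, where the closest control gave 7.44% (p = 0.0563 by Fisher's exact test). Neighbouring genes are not independent replicates, so these p-values are a guide. Whether reads run on past the end of the gene before stays open, because the closest control does not separate it from other effects of an abundant neighbour.

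Of the 354 genes higher at 6, 8 and 10 weeks, 281 were higher in each of the 5 diabetic groups, D8 depleted and D10 repopulated included, and 3 of the 354 were higher in ND repopulated. The ND samples are shared by these comparisons.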
